A study of Homo sapiens with 4 samples.

How the data were processed

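RNA of CaSki cells was measured on 1-colour Agilent arrays in 4 samples, 2 grown as spheres and 2 adherent, grouped by their titles. Per the labels' protocols, spheres were grown for 14 days without attachment in a sphere medium and adherent cells in DMEM with serum, RNA came from a Qiagen kit, and 500 ng of RNA was copied into Cy3-labelled cRNA with an oligo-dT primer at 40 °C. The medium, serum and attachment differ together between the groups. Time in culture may differ too, but a number of days is given for spheres only. The protocols also mention patient samples, which were not analysed here.

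Per the file headers, the arrays were scanned on an Agilent G2505B scanner and read with Feature Extraction 10.5.1.1 on slide 1 and 9.5.1.1 on slide 2. The deposited intensity of a spot (the processed signal) is, per the file headers, background-subtracted and detrended by Feature Extraction, with surrogates for dim spots, and is not normalized between arrays. The deposited spot files also hold raw mean and background intensities and flags. A series table deposited by the authors holds log2 values with no stated scale. Each of its columns correlated at over 0.9999 with the log2 processed signal of the same array and had its 75th percentile at 0, and at least 99.9% of its values lay within 0.02 of the log2 processed signal minus that percentile, which settles its scale, centring and direction. Its column medians were -3.01 and -3.07 for adherent replicates 1 and 2 and -3.10 and -2.92 for sphere replicates 1 and 2. The tool used for that step is not given in the sources used here.

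The processed signals were put on the log2 scale and the 75th percentile of each array was subtracted. Control spots and spots with an outlier flag were left out (between 144 and 164 spots per array), and spots of a probe were averaged. A probe entered the tests if it was well above background on at least 2 of the 4 arrays, which 29617 probes were, and each gene was represented by its probe of highest mean. Of the 41000 probes of 60 bases, 23434 were named through their accession in a RefSeq table of assembly GRCh38.p14, used for names only, 5013 kept the name in the file, of which the design is older, and 12553 had no gene name and were tested by probe. Of the named probes, 2696 had a symbol that the table does not hold. Coordinates are those in the files. Of the 22663 genes tested, 15048 were named. Of the 925 genes called, 191 had several probes, and in 9 of these the probes differed in sign.

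The 75th percentile of the processed signal was 987 and 1393 for adherent replicates 1 and 2, and 992 and 1181 for sphere replicates 1 and 2. Between 26240 and 29860 probes per array were well above background, and between 277 and 487 were saturated. The dimmest probe well above background lay between -6.46 and -4.98 on the log2 scale. A gene below background on every array of one group has only a bound there, and folds of named genes below it on 1 of 2 arrays take that array at its dimmest probe well above background, or at the signal if higher. This held for 136 genes called higher and 81 called lower, and 2 called genes were saturated on every array of a group. Folds of other genes are 2 to the power of the fitted difference.

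Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 2 residual degrees of freedom, 3.83 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The median SE of a log2 difference was 0.44. Gene lists were tested with limma's camera (two-sided, preset correlation 0.01) over the 34 lists, each with at least 5 measured genes, and again with an estimated correlation and with fry. With an estimated correlation, camera takes its p-values on the 2 residual degrees of freedom. A call lost in that form is therefore not by itself a sign that the genes of a list are correlated. The count "adjusted over the list alone" takes the same p-values and adjusts within the list. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Input was read with the R package data.table, version 1.17.8.

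The slide, the Feature Extraction version and the replicate number are the same split. Deviations of same-numbered samples from their group means correlated at 0.40 across genes, and components 1 and 2 of the values took 60.2% of the variance, separating the groups, and 28.3%, separating the slides. Values are therefore also given with the slide as a block and within slides.

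The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 12 genes with the largest rise and the 12 with the largest fall. These were picked among named, called genes with the same sign on both slides, well above background and unsaturated on at least 1 array of each group. It also named up to 4 called members of each list, or, if none passed, up to 2 of smallest p, given as values. Further came up to 5 called genes per direction seen in one group only, by their bound. The CEACAM family, POU5F1, SOX2, NANOG, PROM1, CD44, NOTCH1, JAG1 and HES1 were named whatever their values.

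The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, scaling to the median, the authors' series table, no filter or a stricter filter on dim probes, every probe or the mean of a gene's probes, the replicate number as a block, eBayes with trend and robust, other thresholds, and leaving out each sample. Removing the trend of each array with the GC content of the probes (9 bins), alone and with the block, and scaling to the E1A positive control spots were added after the data were seen.

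The gene test was tested on simulated data for the 22663 genes, with 200 genes changed and 50 at each fold. With SDs drawn from limma's fitted prior, 0% of the 4-fold, 30% of the 8-fold, 70% of the 16-fold and 90% of the 32-fold changes were called, and 3.06% of 98 calls were false. The result depended on the simulated spread. With each gene's own SD, which rests on 2 degrees of freedom, no gene was called, and this was the form tried first. With the moderated SDs 12%, 92%, 98% and 100% were called, and 13.2% of 174 calls were false. In each of the 3 forms, camera called all 3 shifted lists of 30 genes (a shift of 1 on the log2 scale) and none of the other 7 of 10 lists. The simulated values were drawn independently for each gene and array, so they had no correlation between genes and no slide effect. The real lists had estimated correlations such as 0.28 for G2/M and 0.80 for metallothioneins. The simulation therefore cannot show how often camera calls falsely on them.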

Results

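Gene expression was measured in CaSki cells, a human cervical carcinoma line that the labels describe as coming from a metastatic lesion, grown in 2 ways. Spheres were kept for 14 days without attachment in a sphere medium, and adherent cells were grown on a surface in a serum-containing medium. Each group had 2 samples, and each sample was hybridised to 1 one-colour Agilent array of 41000 probes. Each of 2 slides held 1 sphere and 1 adherent sample, and the replicate number was also the slide. Between 64.0% of the probes (adherent replicate 2) and 73.0% (sphere replicate 1) were well above background. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 2 arrays per group, the number of arrays limits the precision. Values are log2 signals relative to the 75th percentile of the array, and each group mean is given with its SD (n = 2).

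The comparison asked which genes differed between CaSki cells grown as spheres and as adherent cells. Spheres had far less RNA of genes that act in cell division and DNA copying, and far more RNA of genes of squamous differentiation, the programme by which stratified epithelium builds its surface layers. Of 45 genes of mitosis 44 were lower, of 44 genes of DNA replication 21 were lower and of 41 squamous genes 21 were higher, and the camera calls of these lists were lost with an estimated correlation (adjusted p = 0.286 for each). Of 22663 genes tested, 443 were higher and 482 lower in spheres (limma, Benjamini-Hochberg adjusted p under 0.05), which is 4.08% of the genes. Named genes made up 336 of those higher and 373 of those lower, and the rest were probes without a gene name, each counted as a gene. The smallest difference that passed was 1.98 on the log2 scale and the median was 3.20. All 925 genes had the same sign on both slides, which was close to fixed in advance, since the same arrays chose these genes by large differences. With the slide as a block 1767 genes passed, 879 higher and 888 lower, the 925 among them. The call of single genes rested on the spread of few arrays: without adherent replicate 1 or without adherent replicate 2 limma called 0 genes, with 2872 and 3033 at an unadjusted p under 0.05, without sphere replicate 1 it called 575, and without sphere replicate 2 it called 919. Normexp background correction with quantile normalization (below, normexp) called 372 genes, and of the 94 called genes that the naming rule picked 35 did not pass with it. Leaving out 1 array moved the fold or bound of 30 of these 94 genes by over 1.5 times. This count takes in every gene set to the dimmest probe well above background on both adherent arrays, whatever its own spread. Without a test, 3379 genes differed by over 2-fold in the same direction on both slides (1658 higher and 1721 lower), against 184 in opposite directions.

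**Figure D1:**
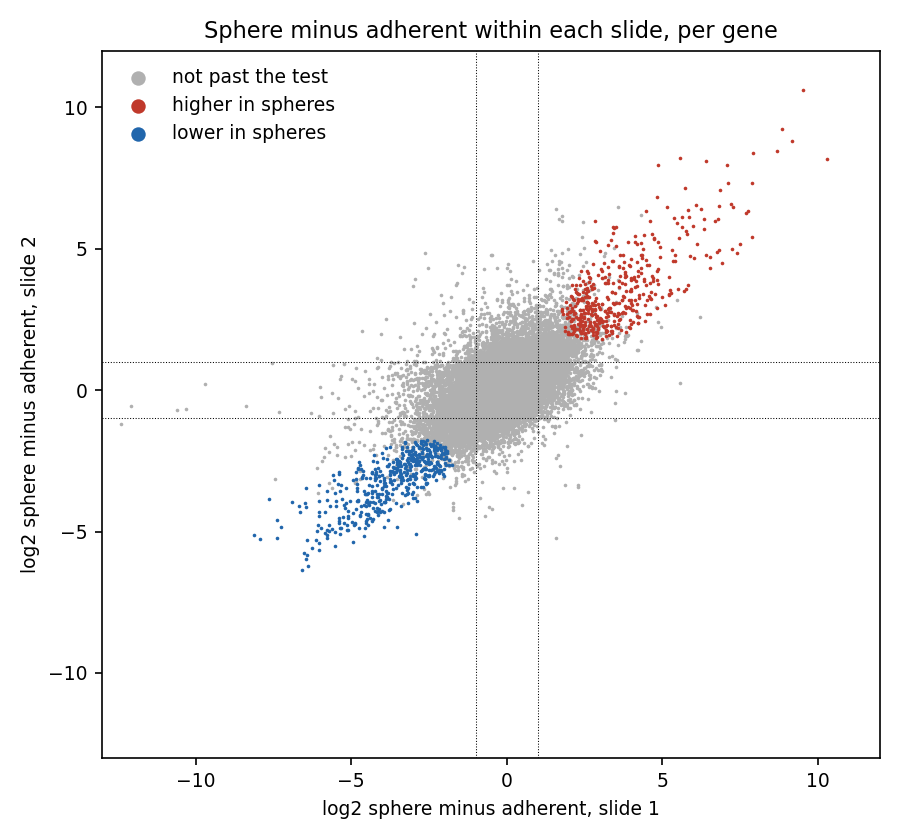
Each point is a gene, with its log2 difference between sphere and adherent cells on slide 1 (x axis) and on slide 2 (y axis); red and blue points are genes that limma called higher or lower, grey points did not pass, and dotted lines mark 2-fold. Genes on the Y chromosome are not drawn. The differences of the 2 slides correlated at 0.67 across genes, which are not independent replicates. The called genes lie in the upper right and lower left, where a call from these same arrays all but places them.

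The genes named here had the largest rise among those well above background and unsaturated on at least 1 array of each group. S100A8, a calcium-binding protein of inflamed and differentiating epithelium, had a mean of 3.93 ± 0.25 in spheres and -4.65 ± 0.43 in adherent cells, a log2 difference of 8.58 (SE 0.43, limma adjusted p = 0.0078), or 382-fold. Its probe lies on chromosome 1 from 150175621 to 150175680 in the files' coordinates, for which a file header of slide 2 names the build hg17. SPRR1B and SPRR3, precursors of the cornified envelope, were higher by at least 162-fold and by 154-fold. CRCT1 was 150-fold and S100A14 118-fold higher, PRR15L at least 104-fold and LCE3D at least 67.9-fold. LCE3D did not pass with normexp (4.51, adjusted p = 0.067). SPINK1, a trypsin inhibitor, was at least 77.1-fold higher, and C1orf38, the transcription factor GRHL3 and SDCBP2 were between 80.6-fold (SDCBP2) and 85.3-fold (C1orf38) higher. Bounds are given for SPRR1B, PRR15L, LCE3D and SPINK1 because 1 of the 2 adherent arrays was not well above background. The ranking used the fitted differences, which take the dim array at its own signal. LCE3D, fitted at 101-fold, therefore stands here, while NUPR1, 73.8-fold higher and above the bound of LCE3D, does not. The aldo-keto reductase AKR1C1, saturated on 1 sphere array, was at least 80.9-fold higher, and its 4 probes ranged from 3.80 to 6.46. MMP1 and S100P, saturated on both sphere arrays and added after their values were seen, were at least 134-fold and 101-fold higher. The other probe of MMP1 had a log2 difference of only 1.92. Leaving out 1 array at a time, SPRR3 ranged from 83.9-fold to 283-fold, and the bounds of LCE3D from 35.5-fold to 130-fold, AKR1C1 from 50.9-fold to 129-fold, MMP1 from 88.8-fold to 201-fold and S100P from 45.9-fold to 222-fold. The 2 probes of CRCT1 differed in size, at 2.36 and 7.23 on the log2 scale.

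The genes with the largest fall included extracellular and mitotic genes. VIT, which encodes an extracellular matrix protein, fell by 6.62 on the log2 scale (SE 0.74, limma adjusted p = 0.016), with -8.11 on slide 1 and -5.12 on slide 2, and did not pass with normexp (-4.07, adjusted p = 0.074). EFEMP1, a fibulin of the extracellular matrix, had a mean of -1.60 ± 0.35 in spheres and 4.70 ± 0.22 in adherent cells, and was 78.3-fold lower. CST6, a cysteine protease inhibitor, was 66.2-fold lower, and the helicase gene PIF1 58.1-fold, although its 3 probes ranged from -5.86 to -1.5. PLAC8, SPC25, KIF20A, FAP, ASPM, SHCBP1 and GTSE1 were between 42.4-fold (GTSE1) and 53.5-fold (PLAC8) lower. The growth factor FGF1, well above background on 1 of the 2 sphere arrays, was at least 34.2-fold lower, and its 3 probes ranged from -6.08 to -3.46. Its place here rests on the fitted fall of 43.0-fold, which takes the dim array at its own signal. CENPF, 38.4-fold lower, fell by more than the bound of FGF1. With normexp SPC25 and GTSE1 did not pass (-4.60 and -3.15, adjusted p = 0.064 and 0.0502). With 1 array left out, VIT ranged from -7.58 to -5.65 on the log2 scale, CST6 from -7.04 to -5.05, PLAC8 from -7.08 to -4.40, SPC25 from -6.78 to -4.64, FAP from -6.36 to -4.61, GTSE1 from -6.56 to -4.25 and the bound of FGF1 from -5.98 to -4.21. SPC25 is a kinetochore protein, KIF20A a mitotic kinesin and ASPM a spindle pole protein.

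Some genes were well above background on both arrays of one group and on no array of the other, so that only a bound on the fold can be given. Of the named genes that limma called, 95 were seen in this way in spheres alone and 43 in adherent cells alone. These counts also depend on the arrays, since adherent replicate 2 had the smallest share of probes well above background (64.0%). MMP10, a secreted metalloproteinase, was at least 487-fold higher in spheres, and the keratin KRT6B at least 352-fold. CEACAM6, DHRS9 and LEMD1 were at least 128-fold, 87.9-fold and 54.7-fold higher. In the other direction, the proliferation marker MKI67 was at least 43.8-fold lower in spheres, DAW1 at least 40.9-fold, MGC24103 at least 34.7-fold, C15orf42 at least 23.6-fold and BNC2 at least 20.6-fold. The probes of MGC24103 and BNC2 start on chromosome 9 at 16516526 and 16403457 in the files' coordinates, so the 2 may not be separate observations. LEMD1 and DAW1 did not pass with normexp (3.37 and -2.66, adjusted p = 0.096 and 0.0502). With 1 array left out the bounds ranged from 222-fold to 557-fold for KRT6B, 81.0-fold to 203-fold for CEACAM6, 5.79 to 7.12 on the log2 scale for DHRS9 and 28.9-fold to 104-fold for LEMD1. These bounds set the brighter group's mean against the higher of the lowest signal well above background and the probe's own signal on each dim array. KRT6B, CEACAM6, DHRS9 and LEMD1 take that lowest signal on both adherent arrays, -6.30 for replicate 1 and -4.98 for replicate 2. Leaving out either array shifts every such bound by the same amount. The ranges of KRT6B, CEACAM6 and DHRS9, and below of CEACAM5, ETV5, EREG, SCGB2A1 and TCP10L2, therefore show this gap between arrays and not a spread of the gene.

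Of 45 measured genes of G2/M and mitosis, 44 were lower in spheres and none was higher, with a median log2 difference of -4.35. Adjusted over the list alone, all 45 were lower. KIF20A fell by 5.52 (SE 0.43) and by the same size on both slides, ASPM by 5.46 (SE 0.40) and CENPF, a kinetochore protein, by 5.26 (SE 0.44), and MKI67 had the bound above. ECT2 alone did not pass. The list's median was -4.47 on slide 1 and -4.30 on slide 2. The camera test placed it below the other genes (adjusted p = 1.95e-48). The call was lost with an estimated correlation, a form that rests on 2 residual degrees of freedom (adjusted p = 0.286).

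Of 44 measured genes of G1/S and DNA replication, 21 were lower and none higher, with a median of -2.06, and 40 were lower when adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, fell by 4.65 (SE 0.49), the exonuclease EXO1 by 4.58 (SE 0.46) and the replication factor MCM10 by 4.33 (SE 0.45). CLSPN, a checkpoint adaptor, was not well above background in spheres and was at least 9.52-fold lower, and did not pass with normexp (-1.32, adjusted p = 0.092). The slide medians were -2.18 and -1.97. Camera called the list lower (adjusted p = 3.13e-26), with an adjusted p of 0.286 with an estimated correlation.

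Of 41 measured genes of squamous differentiation, 21 were higher in spheres and none lower, with a median of 2.40, and 27 were higher when adjusted over the list alone. KRT6B, S100A8, SPRR1B and SPRR3 led the list, with the values above. The slide medians were 2.34 and 2.57. Camera called the list higher (adjusted p = 2.25e-21), with an adjusted p of 0.286 with an estimated correlation. In the list of basal keratinocyte and hemidesmosome genes 1 of 21 was higher, the collagen receptor subunit ITGA2 at 2.83 (SE 0.45), and the same 1 when adjusted over the list alone. ITGA2 did not pass with normexp (2.23, adjusted p = 0.066) or without sphere replicate 1 (2.61, adjusted p = 0.080). That list had a median of 0.24 and was called higher by camera (adjusted p = 0.019), not with an estimated correlation (adjusted p = 0.515), without sphere replicate 1 (adjusted p = 0.062) or without adherent replicate 2 (adjusted p = 0.086). Its median was -0.14 when arrays were scaled to control spots, a scaling that moved the median of all genes to -0.39.

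The CEACAM family, cell surface glycoproteins of which only some are also known as CD66, had 3 of the 7 measured members of the list higher in spheres, or 4 when adjusted over the list alone. CEACAM6 was at least 128-fold and CEACAM5 at least 12.7-fold higher (8.03-fold to 20.1-fold with 1 array left out), both below the background limit in adherent cells. CEACAM7, well above background on 1 adherent array, rose by 3.64 (SE 0.44, limma adjusted p = 0.017). With normexp CEACAM5 had 2.0 and CEACAM7 1.89, and neither passed (adjusted p = 0.091 and 0.065). CEACAM1 differed by 3.58 (SE 0.71, with another of its probes at 0.47) and did not pass (adjusted p = 0.057; 0.029 with the slide as a block). CEACAM3 had -0.13, with a second probe at 4.43, CEACAM4, well above background on 1 adherent array, had 0.05 and CEACAM19 had 0.36. CEACAM20, which the list does not hold and which was added after its values were seen, had -0.38 and did not pass. CEACAM8 and CEACAM21 were too dim to be tested. The list's median was 3.58 (1.97 over 8 genes with CEACAM20), with 2.35 on slide 1 and 4.21 on slide 2, and camera called it higher (adjusted p = 0.00016; 0.454 with an estimated correlation). The members are near copies of each other, and binding of one member's RNA to another's probe was not measured.

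**Figure D2:**
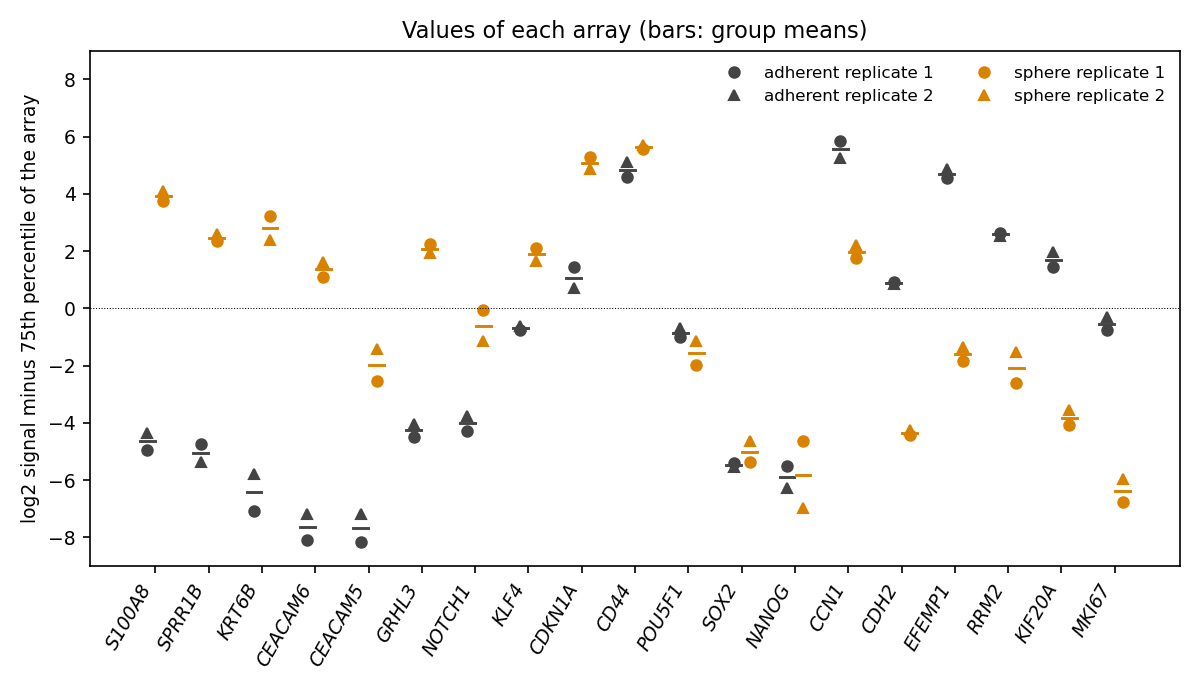
Values of each array for 19 named genes, as log2 signal minus the array's 75th percentile (y axis), for adherent (grey) and sphere (orange) cells, with circles for replicate 1, triangles for replicate 2 and bars for group means (n = 2). S100A8 lies near 3.93 in spheres and -4.65 in adherent cells, and MKI67 at -6.37 and -0.53. Both sphere values of MKI67 and both adherent values of KRT6B, CEACAM6 and CEACAM5 are not well above background. The same holds for 1 adherent value each of SPRR1B and SOX2 and for 1 value of NANOG in each group.

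Among stem cell and pluripotency markers, 1 of 20 measured genes passed, over all genes and adjusted over the list alone. It was KLF4, a transcription factor that also acts in epithelial differentiation, at 2.58 (SE 0.40, limma adjusted p = 0.030). It did not pass with normexp (adjusted p = 0.0502), when scaled to control spots (0.057) or without sphere replicate 1 (0.079). POU5F1 had a log2 difference of -0.71 (SE 0.46), SOX2 0.48 (SE 0.43), NANOG 0.07 (SE 0.81) and CD44 0.78 (SE 0.40), and none of these passed (adjusted p between 0.381 and 0.982). NANOG was well above background on 1 array of each group and SOX2 on 1 adherent array; with dim arrays at the background limit they had 0.17 and 0.19. PROM1 was not well above background on any array. The list had a median of 0.14, with -0.045 on slide 1 and -0.088 on slide 2, and was not called by camera (adjusted p = 0.673).

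Of 32 measured Notch pathway genes 2 were higher and 1 lower, and 5 were higher and 1 lower when adjusted over the list alone. The receptor NOTCH1 rose by 3.40 (SE 0.52, limma adjusted p = 0.030), with 4.22 on slide 1 and 2.59 on slide 2, and HES2 by 2.98 (SE 0.38). LFNG, a glycosyltransferase that modifies Notch receptors, had -4.98 (SE 0.70), with its other probe at -0.17 and a range from -5.99 to -3.98 with 1 array left out. The ligand JAG1 had -0.25 (SE 0.39) and the target HES1 1.54 (SE 0.39, adjusted p = 0.104). NOTCH1 did not pass without sphere replicate 1 (2.85, adjusted p = 0.057) or with normexp (2.20, adjusted p = 0.079), and LFNG not with the mean of its probes (-2.58, adjusted p = 0.083). Camera did not call the list (adjusted p = 0.270), whose median was -0.03 and whose mean was 0.18, in the direction of the test.

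Of 16 Wnt/beta-catenin targets EPHB3 was higher, at 4.18, and TNFRSF19 (at least 10-fold) and SP5 (-2.17, with probes up to 0.06) were lower, and 2 were higher and 2 lower adjusted over the list alone. TNFRSF19 did not pass with normexp (-1.58, adjusted p = 0.059), and SP5 not with normexp (-1.79, adjusted p = 0.072), with no filter (0.075), with the mean of its probes (-1.42, 0.330), or without sphere replicate 1 (0.101) or 2 (0.078). The list had a median of -0.41 (camera adjusted p = 0.336). Of 16 retinoid response genes the dehydrogenase DHRS9 was higher, and CYP26B1, which breaks down retinoic acid, and the retinol transporter STRA6 were lower, at -3.51 and -2.75. STRA6 did not pass with normexp (-1.29, adjusted p = 0.130), with no filter (0.0505) or without sphere replicate 1 (0.085). Adjusted over the list alone 1 was higher and 4 lower, and the median was -0.42 (camera adjusted p = 0.234). None of 9 Hedgehog pathway genes passed, also over the list alone. GLI1, well above background on 1 array of each group, had -1.52 (-1.05 with dim arrays at the background limit) and SUFU -0.66, with another probe of SUFU at 0.60, and the median was -0.0037 (camera adjusted p = 0.662).

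Of 23 measured mesenchymal genes 7 were lower and 2 higher in spheres, and 11 and 2 when adjusted over the list alone. FAP, a surface protease of activated fibroblasts, fell by 5.48 (SE 0.66), N-cadherin (CDH2) by 5.22 (SE 0.38), and the actin-binding protein CALD1 by 4.29 (SE 0.65; with normexp -4.02, adjusted p = 0.069; -5.03 to -3.55 with 1 array left out). The median was -0.93 (camera adjusted p = 0.00023; 0.515 with an estimated correlation), with slide medians of -1.29 and -0.79. Of 33 epithelial junction genes 5 were higher and none lower, and 10 were higher and 1 lower adjusted over the list alone. The desmosomal genes DSG3, PKP1 and DSC3 rose by 3.94, 3.38 and 2.35, and the tight junction gene CLDN1 by 3.88. With 1 array left out CLDN1 ranged from 3.17 to 4.58 and PKP1 from 2.69 to 4.07. PKP1, well above background on 1 adherent array, DSC3 and CLDN1 did not pass with normexp (1.46, 1.77 and 3.79, adjusted p = 0.091, 0.051 and 0.065) or without sphere replicate 1 (adjusted p = 0.057, 0.110 and 0.057). PKP1 and DSC3 did not pass without sphere replicate 2 either (adjusted p = 0.071 and 0.056), PKP1 not with quantile normalization (0.055), and DSC3 not with no filter (0.068) or scaled to control spots (0.112). The junction list had a median of 1.16, with 1.18 and 1.09 on the slides (camera adjusted p = 9.88e-07; 0.286 with an estimated correlation).

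Of 22 YAP/TAZ targets 5 were lower and none higher, and 8 were lower and 2 higher adjusted over the list alone. The matricellular gene CCN1 fell by 3.57 (SE 0.43), RBMS3 by 3.65 and the receptor kinase AXL by 3.22, and TGFB2 was at least 9.02-fold lower (-3.97 to -2.38 on the log2 scale with 1 array left out). AXL and TGFB2 did not pass with normexp (-3.03 and -1.54, adjusted p = 0.05004 and 0.148). The median was -1.04, with -1.42 and -0.84 on the slides (camera adjusted p = 9.93e-06; 0.385 with an estimated correlation). Of 20 genes of columnar and mucin-producing epithelium the mucin MUC20 was higher, at 4.18, and the keratin KRT7 lower, at -2.48, and 4 were higher and 1 lower adjusted over the list alone. MUC20 did not pass with normexp (3.67, adjusted p = 0.052), and KRT7 not with no filter (0.0505) or without sphere replicate 1 (0.068) or 2 (0.058). That list's median was 0.29, with 0.0017 on slide 1 and 0.85 on slide 2. Camera called it higher (adjusted p = 0.039; 0.470 with an estimated correlation), but not without sphere replicate 2 (adjusted p = 0.070), without adherent replicate 2 (adjusted p = 0.181), or with normexp (adjusted p = 0.086). Its median was -0.089 when scaled to control spots.

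**Figure D3:**
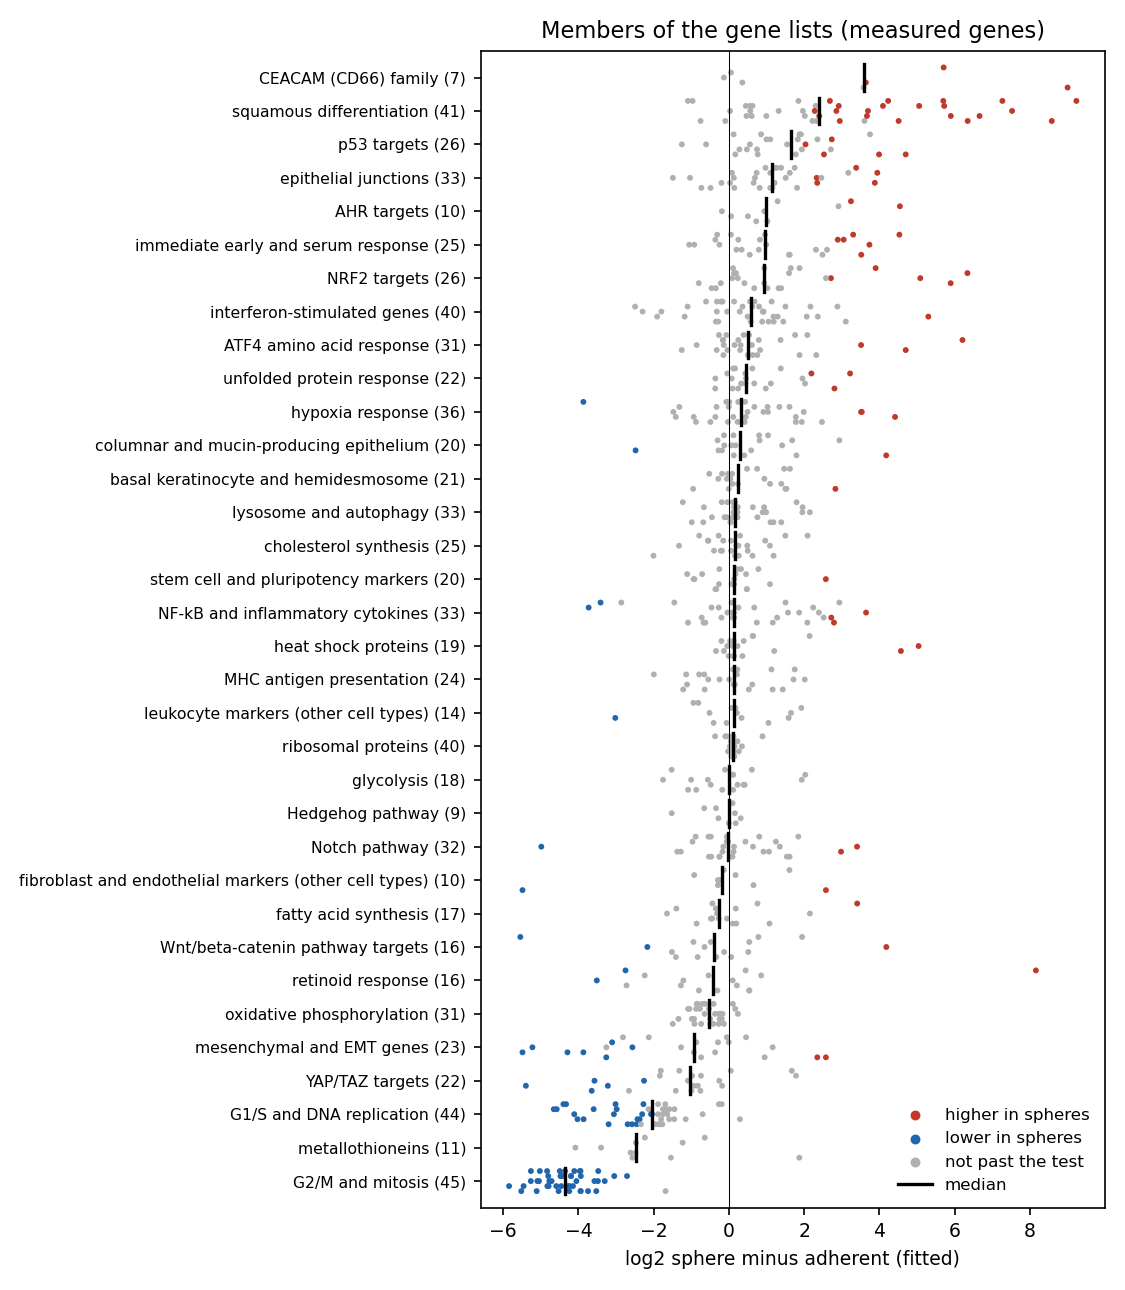
Each point is a measured gene of a list, placed by its fitted log2 difference between spheres and adherent cells (x axis); rows are the 34 lists with the number of measured genes, black bars are medians, and red and blue points were called higher or lower by limma. The mitotic genes lie lowest, with a median of -4.35, and the CEACAM list of 7 has a median of 3.58 and squamous differentiation of 2.40.

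Of 25 immediate early and serum response genes 6 were higher and none lower, or 10 when adjusted over the list alone. DUSP5 and DUSP6, phosphatases of the ERK pathway, rose by 4.53 and 3.52, the ERK pathway inhibitor SPRY2 by 3.73, and ETV5 was at least 5.88-fold higher (3.71-fold to 9.31-fold with 1 array left out). ETV5 did not pass with normexp (0.99, adjusted p = 0.161), quantile normalization (0.061) or without sphere replicate 1 (0.076), nor DUSP6 without sphere replicate 1 (0.051). The median was 0.96, with 0.61 and 1.73 on the slides (camera adjusted p = 6.56e-06; 0.286 with an estimated correlation). Of 26 p53 targets 5 were higher, or 12 adjusted over the list alone. CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 3.99 (SE 0.45), the stress cytokine GDF15 by 4.70 (SE 0.48), PLK3 by 2.73 and ZMAT3 by 2.53. PLK3 and ZMAT3 did not pass with no filter (adjusted p = 0.052 and 0.051) or without sphere replicate 1 (0.070 and 0.079) or 2 (0.068 and 0.051), nor ZMAT3 with normexp (1.35, 0.088) or scaled to control spots (0.066). That list had a median of 1.66 over all 4 arrays and slide medians of 1.35 and 1.27 (camera adjusted p = 1.3e-08; 0.327 with an estimated correlation).

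Of 26 NRF2 targets 5 were higher, or 6 adjusted over the list alone. AKR1C1, AKR1B10 and AKR1C3, aldo-keto reductases, rose by at least 6.34 (1 sphere array saturated), 5.09 and 3.90, and the drug exporter ABCC3 by 5.89 (with normexp 4.77, adjusted p = 0.056). With 1 array left out AKR1C1 ranged from 5.67 to 7.01, AKR1C3 from 3.28 to 4.51 and ABCC3 from 5.17 to 6.61. The median was 0.94, with 0.85 and 0.42 on the slides (camera adjusted p = 1.41e-05; 0.454 with an estimated correlation). Of 10 targets of the aryl hydrocarbon receptor SERPINB2 was higher, by 4.54, and EREG at least 5.21-fold (3.29-fold to 8.26-fold with 1 array left out; with normexp 0.94, adjusted p = 0.131), and 3 were higher adjusted over the list alone. The median was 0.98, with 1.45 and 0.87 on the slides (camera adjusted p = 0.00050; 0.327 with an estimated correlation).

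Of 22 genes of the unfolded protein response 3 were higher, or 5 adjusted over the list alone: DDIT3 rose by 3.22, the chaperone DNAJB9 by 2.80 and ERN1 by 2.19, although the probes of ERN1 ranged from -0.58 to 2.19. DNAJB9 did not pass without sphere replicate 2 (adjusted p = 0.055). ERN1 did not pass with normexp (1.67, adjusted p = 0.067), quantile normalization (0.053), median scaling (0.0503), no filter (0.081), the mean of its probes (0.88, 0.314) or control spot scaling (0.164), nor without sphere replicate 1 (0.126) or 2 (0.066). The median was 0.45 (slides 0.41 and 0.47, camera adjusted p = 0.00031; 0.286 with an estimated correlation). Of 31 genes of the ATF4 amino acid response 3 were higher, or 6 adjusted over the list alone, namely NUPR1 at 6.21, GDF15 and STC2 (3.51, and 2.92 to 4.11 with 1 array left out). The median was 0.50 (slides 0.53 and 0.54). Camera called this list higher (adjusted p = 0.0018; 0.543 with an estimated correlation), but not without sphere replicate 1 (adjusted p = 0.094). Of 19 heat shock proteins CRYAB and HSPA6 were higher, at 5.04 and 4.57 (HSPA6 from 3.93 to 5.21 with 1 array left out), or 3 adjusted over the list alone. The median was 0.14 (slides 0.53 and 0.22, camera adjusted p = 0.019; 0.388 with an estimated correlation), and without sphere replicate 1 it was -0.015 (adjusted p = 0.188). When scaled to control spots the heat shock median was -0.25.

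Of 36 hypoxia response genes 3 were higher, the glucose transporter SLC2A3 (at least 9.60-fold, and 4.45-fold to 20.7-fold with 1 array left out), the carbonic anhydrase CA12 (at least 9.70-fold, with 1 adherent array well above background) and STC2 (3.51, and 2.92 to 4.11 with 1 array left out), and 1 was lower, with 5 and 1 adjusted over the list alone. None of these 3 passed with normexp (1.65, 1.53 and 3.49, adjusted p = 0.235, 0.065 and 0.0502), nor SLC2A3 with quantile normalization (0.059). The hypoxia list had a median of 0.33, but -0.25 on slide 1 and 1.34 on slide 2. Camera called it higher (adjusted p = 0.024; 0.803 with an estimated correlation), but the median was -0.21 without sphere replicate 2 (adjusted p = 0.670) and 0.16 without adherent replicate 2 (adjusted p = 0.166). Scaled to control spots the hypoxia median was -0.049. Of 40 interferon-stimulated genes OASL was higher (at least 31.8-fold, and 16.5-fold to 61.4-fold with 1 array left out; with normexp 2.65, adjusted p = 0.134), also over the list alone. The interferon list had a median of 0.60, with -0.30 on slide 1 and 1.14 on slide 2. Camera called it higher (adjusted p = 0.044; 0.824 with an estimated correlation), but not without sphere replicate 2 (median -0.036, adjusted p = 0.741), adherent replicate 1 (adjusted p = 0.059) or adherent replicate 2 (adjusted p = 0.097). None of 11 metallothioneins passed over all genes, and 1 was higher and 2 lower adjusted over the list alone. MT1M had -4.08 (adjusted p = 0.051; 0.011 with the slide as a block) and MT3 1.87 (adjusted p = 0.094; 0.048 with the slide as a block), with its other probe at -0.17. The metallothionein median was -2.47, with -4.01 on slide 1 and -0.72 on slide 2 (camera adjusted p = 0.0021; 0.577 with an estimated correlation).

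Among the metabolic lists, none of 31 genes of oxidative phosphorylation passed, also over the list alone, and camera called the list lower (adjusted p = 0.0014; 0.477 with an estimated correlation), with a median of -0.53 and slide medians of -0.62 and -0.41. NDUFA9 had -1.49 and ATP5PB -1.05. None of 33 lysosome and autophagy genes passed, also over the list alone, with WIPI1 at 1.95 and NEU1 at 1.80; with the slide as a block 4 were higher, WIPI1 and NEU1 among them (adjusted p = 0.035 and 0.043). Camera called that list higher (adjusted p = 0.033; 0.385 with an estimated correlation), with a median of 0.17 and slide medians of 0.26 and 0.30. The lysosome call was lost without sphere replicate 1 (adjusted p = 0.088), sphere replicate 2 (adjusted p = 0.062) or adherent replicate 1 (adjusted p = 0.090), and when scaled to control spots, where the median was -0.22 (adjusted p = 0.099).

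Camera did not call glycolysis (median 0.0047, mean -0.089, slides -0.52 and 0.24, 18 genes, adjusted p = 0.662), cholesterol synthesis (median 0.16, 25 genes, adjusted p = 0.637) or fatty acid synthesis (median -0.27, mean 0.096, slides 0.15 and -0.47, 17 genes, adjusted p = 0.926). In these lists ACSS2, which makes acetyl-CoA from acetate, was higher, at 3.41, but not with normexp (3.20, adjusted p = 0.082) or without sphere replicate 1 (2.75, adjusted p = 0.056; 2.75 to 4.06 with 1 array left out). Adjusted over the list alone, 1 glycolysis gene, 0 cholesterol genes and 1 fatty acid gene were higher. HK2, saturated on 1 sphere array, had 1.94 (adjusted p = 0.054), PGAM1 -1.75, ACAT2 -2.00 (adjusted p = 0.051) and TM7SF2 1.5; HK2 and ACAT2 passed with the slide as a block (adjusted p = 0.033 and 0.032). Without sphere replicate 2 camera called cholesterol synthesis higher (adjusted p = 0.042). None of 40 ribosomal protein genes passed, also over the list alone (median 0.11, camera adjusted p = 0.420), with RPS9 at 0.89 and RPL4, saturated on 1 array of each group, at 0.35. Without adherent replicate 1 that list was called higher (median 0.38, adjusted p = 0.039).

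Of 33 genes of NF-kB and inflammatory cytokines 3 were higher and 2 lower, with 8 and 3 adjusted over the list alone. The complement gene CFB rose by 3.64 and the interleukin 1 antagonist IL1RN by 2.79, with its other probe at 0.70. The cytokine IL6 fell by 3.73 (SE 0.39), and the chemokine CXCL6 was at least 7.62-fold lower. CFB, well above background on 1 adherent array, CXCL6 and IL1RN did not pass with normexp (1.64, -1.22 and 2.77, adjusted p = 0.072, 0.155 and 0.061), nor IL1RN with no filter (0.054), the mean of its probes (1.75, 0.079) or without sphere replicate 2 (0.075). The median was 0.14 and camera did not call the list (adjusted p = 0.062), but it did with the slide as a block (adjusted p = 0.037), without sphere replicate 1 (0.027) and without adherent replicate 2 (0.0095). None of 24 genes of MHC antigen presentation passed, also over the list alone (median 0.13, camera adjusted p = 0.442). HLA-DRA was well above background in spheres only, at least 1.52-fold (adjusted p = 0.054), and NLRC5 had 1.72 (adjusted p = 0.079); with the slide as a block their adjusted p were 0.034 and 0.048.

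Markers of other cell types did not move as groups. Of 14 leukocyte markers the integrin ITGB2 was lower, at -3.02, also over the list alone, but not without sphere replicate 1 (adjusted p = 0.065; list median 0.12, camera adjusted p = 0.662). Of 10 fibroblast and endothelial markers ACTA2 was higher, at 2.58, and FAP lower, with the same counts over the list alone; ACTA2 did not pass without sphere replicate 1 (adjusted p = 0.078) or scaled to control spots (0.056). That list's median of -0.18 and mean of -0.23 lay against the direction of its test, and its slide medians were -0.50 and 0.35 (camera adjusted p = 0.967).

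Over the 34 lists, camera with a preset correlation called 15 higher and 6 lower, and 0 with an estimated correlation (smallest adjusted p = 0.286), while fry, which asks whether a list's genes move one way without comparing them with other genes, called 6 (smallest adjusted p = 0.022). The estimated correlation was 0.0070 for squamous differentiation and -0.018 for epithelial junctions, both below the preset 0.01. Their unadjusted camera p in that form were 0.0095 and 0.026. For these lists a higher correlation did not cost the call, and the form's 2 residual degrees of freedom limit it. Other lists had higher estimates, up to 0.80 for metallothioneins.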

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

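The measure in this part was chosen after the data were seen. The E1A positive control spots, which the comparisons of genes use only in an added alternative scaling, gave a signal of 7.10 times the array's 75th percentile in sphere replicate 2, above the level of adherent replicates 1 and 2 (4.04 and 3.80) and of sphere replicate 1 (3.68). The difference between the spheres lies between the replicates of one group and was not tested.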

How the results depend on the processing

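The alternatives with GC correction or E1A scaling were chosen after the data were seen. The 925 genes changed (443 higher, 482 lower), the 3379 genes over 2-fold on both slides and the 21 lists called moved as follows; unless a reason is given, the cause was not tested. Normexp with quantile normalization gave 372 genes (146 higher, 226 lower; 351 of the 925 among them) and 1915 genes over 2-fold on both slides. The replicate block gave 1767 (879 higher, 888 lower), with all 925 among them, and the replicate block with GC correction 2329 (1129 higher, 1200 lower). An adjusted p under 0.1 gave 1718 (856 higher, 862 lower), and 1.5-fold in place of 2-fold gave 6167 genes on both slides, as looser thresholds must. E1A scaling gave 1427 genes, 442 higher and 985 lower, or 31.0% higher against 47.9%, and moved the median of all genes from -0.0075 to -0.39. Its fit had infinite prior degrees of freedom, so limma gave all genes 1 common spread. The adjusted p-values of single genes with control spot scaling, given above, therefore do not weigh each gene's own spread. The other alternatives run on all 4 arrays gave between 640 genes (no filter, with 31576 tested) and 1352 (eBayes with trend and robust). The slide as a random block could not be fitted with 4 arrays on 2 slides and was not run.

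Leaving out each sample gave between 0 and 919 genes changed, 0 to 338 higher, 0 to 581 lower, and 18 to 20 lists. Such a fit has 1 residual degree of freedom and assumes that the lone sample varies like the other group. Limma called 575 without sphere replicate 1 (314 higher, 261 lower; 463 of the 925), 919 without sphere replicate 2 (627 of the 925), and 0 without adherent replicate 1 or 2, where the smallest adjusted p were 0.079 and 0.053, and 2872 and 3033 genes had an unadjusted p under 0.05.

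With an estimated correlation 0 of 34 lists were called, and fry called 6. The 2 cell cycle lists, squamous differentiation, CEACAM, mesenchymal genes, epithelial junctions, oxidative phosphorylation, immediate early genes, YAP/TAZ, NRF2, p53 and AHR targets, the unfolded protein response and metallothioneins kept their direction and call under every other alternative run on them. Their medians ranged over these alternatives from -4.74 to -3.55 (G2/M), -2.44 to -1.78 (G1/S), 1.70 to 2.86 (squamous), 1.17 to 3.90 (CEACAM), -2.56 to -0.54 (mesenchymal), 0.78 to 1.24 (junctions), -0.91 to -0.39 (oxidative phosphorylation), 0.54 to 1.39 (immediate early), -1.48 to -0.84 (YAP/TAZ), 0.42 to 1.0 (NRF2), 1.19 to 1.79 (p53), 0.60 to 1.36 (AHR), 0.066 to 0.58 (unfolded protein) and -3.77 to -0.99 (metallothioneins). Losses of a call, by adjusted p: columnar epithelium with normexp (0.086), GC correction (0.139) and the replicate block with GC correction (0.156), interferon-stimulated genes with the stricter filter (0.110) and with every probe (0.081), and lysosome and autophagy with E1A scaling (0.099). NF-kB was called with no filter (0.026), the stricter filter (0.025), every probe (0.0092), the replicate block (0.037) and the replicate block with GC correction (0.032), and MHC antigen presentation with every probe (0.0092).

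The direction of a test turned for these lists, none of which passed there; values are medians. Fatty acid synthesis had -0.16 with no filter, -0.27 with the stricter filter, 0.17 with every probe, -0.051 with the mean of probes, -0.22 with GC correction and with the replicate block with GC correction, -0.65 with E1A scaling, and -0.51 to -0.033 leaving out samples. Fibroblast and endothelial markers had -0.25 with quantile normalization, -0.29 with no filter, -0.21 with the stricter filter, -0.26 with every probe and with the mean of probes, -0.34 with GC correction and with the replicate block with GC correction, -0.56 with E1A scaling, and -0.39 to 0.34 leaving out samples. Leukocyte markers had 0.036 with normexp, -0.26 with no filter, 0.0060 with the stricter filter, and -0.48 to 0.77 leaving out samples. Stem cell markers had 0.084 with every probe. Leaving out samples, hypoxia ranged from -0.21 to 1.06, interferon-stimulated genes from -0.036 to 1.14, glycolysis from -0.38 to 0.11, cholesterol synthesis from -0.22 to 0.32 and ribosomal proteins from -0.18 to 0.38.

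Log2 differences that changed sign belonged to genes that did not pass. NANOG had -0.078 with normexp, -0.028 with quantile normalization, -0.32 with E1A scaling and -1.10 to 1.24 leaving out samples. CEACAM4 had -9.1e-05 with quantile normalization, -0.029 with GC correction and with the replicate block with GC correction, -0.33 with E1A scaling and -0.40 to 0.51 leaving out samples. CEACAM3 had 2.15 with the mean of its probes and -0.69 to 0.42 leaving out samples. SUFU had 0.043 with the mean of its probes, and E1A scaling gave CEACAM19 -0.025 and RPL4 -0.036. Among the other values of named genes with all 4 arrays, 1400 kept their side of the threshold, 57 fell below it and 59 rose above it. Leaving out a sample, 258 kept it, 214 fell below it and 2 rose above it. Signal over background limits 136 genes called higher and 81 called lower to a bound.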

Other observations

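The tests in this part were chosen after the results were seen, except the share of called genes that stayed called after GC correction. The bounds for that share were set before its result, but GC correction itself was added after the data were seen. Families of named genes, formed from the letters that open their symbols, were tested for an excess of called genes against the 15048 named genes tested (one-sided hypergeometric test, Benjamini-Hochberg over 470 families in both directions). Kallikreins, serine proteases of which only some act at the skin surface, had 6 of 12 measured genes higher in spheres (hypergeometric adjusted p = 3.42e-05). These were KLK4, KLK5, KLK7, KLK8, KLK10 and KLK11. KLK8, saturated on 1 sphere array, was at least 50.4-fold higher (30.6 to 83.1 with 1 array left out) and KLK5 33.3-fold. Clade B serpins had 5 of 11 higher (adjusted p = 0.00052), with SERPINB3 52.7-fold and SERPINB4 51.9-fold higher. Matrix metalloproteinases had 5 of 17 higher (adjusted p = 0.0036): MMP1, saturated in spheres, was at least 134-fold higher (88.8 to 201 with 1 array left out), and MMP3 10.7-fold (5.77 to 19.9), although the family's median was 0.14. The other probe of MMP1 gave a log2 difference of 1.92.

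Secretoglobins, small secreted proteins of glandular epithelia, had 3 of 6 genes higher in spheres (adjusted p = 0.022). SCGB1D1 was at least 12.9-fold (7.51 to 22.2 with 1 array left out), SCGB1D2 at least 10.8-fold (6.55 to 17.8) and SCGB2A1 at least 2.48-fold higher (1.57 to 3.93). S100 genes had 5 of 16 higher (adjusted p = 0.0030), with S100P, saturated in spheres, at least 101-fold (45.9 to 222), and SPRR genes 5 of 7 (adjusted p = 3.42e-05). Symbols that open with TCP had 3 of 5 higher (adjusted p = 0.013). These 3 lie on chromosomes 21, 6 and 12, and shared letters alone do not make them related genes. TCP10L2 among them was at least 1.93-fold higher (1.22 to 3.06 with 1 array left out). Kinesins had 9 of 30 lower (adjusted p = 2.72e-05), and CDCA genes, also grouped by letters alone, 4 of 7 (adjusted p = 0.0023). Members of both groups are in the mitosis list above, so these counts in part repeat its fall. The squamous list likewise holds KLK5, KLK7, KLK10, SPRR1B, SPRR2D, SPRR3, S100A8, S100A9, S100A12, SERPINB3 and SERPINB4. The counts of kallikreins, SPRR genes, S100 genes and clade B serpins therefore in part repeat that list's rise. CEACAM genes, with 3 of 8 higher, did not pass (adjusted p = 0.053). Many of these families hold near copies on neighbouring stretches of a chromosome, and binding of one copy's RNA to another's probe was not measured.

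On slide 1, 6 probes without a position in the human genome were far lower in spheres than in adherent cells. Their median was -8.40 in sphere replicate 1, where none was above background, and 2.37, -0.48 and -0.70 in adherent replicates 1 and 2 and sphere replicate 2, where all 6 were. Probes with this pattern made up 1.89% of 317 measured probes without a genome position and 0.157% of 29300 with one (Fisher's exact test, two-sided, p = 1.93e-05). RNA of another organism, such as a mycoplasma, in 3 of the 4 samples is a candidate explanation that cannot be told apart here: the pattern was defined from these probes, so the shares restate what prompted it, and no sequence search was run. Growth as spheres is argued against by sphere replicate 2. Probes without a position that were chosen on the other 3 arrays alone, by the same gap, were the same 6, and there sphere replicate 2 was higher than sphere replicate 1 by a median of 7.41 (4.79 to 9.74). The other probes without a position had a median difference from the other arrays of -0.22. Those values are relative to each array's 75th percentile, which removes overall dimness, so they cannot test for a dim array. Against a dim array stands the share of all probes well above background. It was 73.0% on sphere replicate 1 and between 64.0% and 72.6% on the other arrays. None of the 6 was called between the groups, and whether such RNA goes with other gene changes stays open, with 1 sample of the kind.

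The replicates of a group differed with probe GC content. Across genes, GC content correlated at -0.27 with sphere replicate 1 minus 2, at -0.26 with adherent replicate 1 minus 2, and at 0.053 with the difference between groups. Probe GC content as the main source of the replicate spread is argued against, since removing the trend lowered the SD of the sphere replicate difference by only 4.95%. This lay just under a bound of 5% that was set after the results were seen. As a source of the calls it is argued against as well: 905 of the 925 genes (97.8%) stayed called, and their median size was 3.21 against 3.20. Slide and Feature Extraction version go with the trend, and what set it may lie in labelling or scanning, which no value here tells apart.

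The fall of mitotic genes with the rise of squamous genes may reflect growth as spheres, a hypothesis found and tested on the same data. Over 5 scalings the medians of the 2 lists stayed on opposite sides of 0 and at least 1.70 away from it. Scaling to the median or to control spots shifts all genes of an array alike. It cannot change the gap between the lists, so these scalings decide nothing here. Quantile normalization, with and without normexp, and GC correction can change the gap, and they argue against scaling as the source. The slide or Feature Extraction version is argued against by the design, since each slide held both groups. The slide medians given above stayed at least 2.34 away from 0. RNA of a different cell line in one of the groups cannot be told apart: the SD of medians over 435 windows of 50 neighbouring genes was 1.32 times that of shuffled genes, between the bounds set for neither (1.2) and a clear shift (2), and co-regulated neighbours raise it too. Medium, serum and attachment differ together between the groups, and days in culture, given for spheres only, may differ too. None was tested on its own.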
